A study of Rhodopseudomonas palustris CGA009 with 10 samples.

How the data were processed

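The samples are 10 RNA libraries of wild-type R. palustris CGA009, 2 in each of 5 groups: PM (replicates 1 and 3), LowS (1 and 2), LowS_MTEtOH (2 and 3), NoMo (2 and 3) and NoMo_MTEtOH (1 and 2). Per the labels' protocols, cells grew anaerobically with 10 mM malate, total RNA was depleted of rRNA, and libraries were sequenced on Illumina as 2x150 bp pairs. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0, StringTie 2.1.5 and DESeq2 1.20.0 were used. The deposited count table holds whole-number counts per gene that the authors made with featureCounts 2.0.1, per the file headers, for 4980 features in 10 sample columns, all of which were used. The command in the header sets no strand option, so reads of a gene and of a transcript antisense to it cannot be told apart, nor can reads in overlapping genes, and by that program's default reads that map to several places are not counted. Genes that share a symbol with another feature (the pufB, groL, exbB, nirK, nifH, nifE and nifN copies) are named by locus tag, and copies here means a shared symbol only. Their sequences were not compared, so where copies are alike their levels are uncertain. The authors' deposited spreadsheet lists genes changed against PM with a log2 fold change, a q-value rounded to 2 decimals, and per-feature summaries over libraries on a log2 scale. How the authors fitted it is not stated.

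Of the 4980 features, 4974 have their locus tag in the reference table of the organism, 4878 of them with the same start and end, and 962 carry a symbol, 155 of which are shared with another feature. Every feature has a locus tag, by which genes without a symbol are named. Coordinates are those of the deposited count table, 1-based, on the chromosome. The locus tags in the authors' spreadsheet are numbered differently from those of the count table. Joined by the same tag, fold changes correlated at r = 0.261 and 0.358 across genes with those computed here, so entries were matched instead by their order along the chromosome and by the minimum, maximum, mean and SD that the authors give, with a tolerance of 0.5 on the log2 scale and 2 of 4 neighbours sharing the same offset. Gene names and fold changes took no part in the match. The 4 lists hold 1092 entries for 831 features. Of these features 799 have a tag number below 24800, a limit set for the match, and 632 of the 799 (79.1%) were matched. Features above the limit were left out of the match, although the count table also holds tags above it. All 68 matched entries with a gene name that is a symbol in the reference carried that symbol on the matched gene, the fold changes then correlated at r = 0.999 over 347 and 0.998 over 505 genes, and in 5 simulated runs at least 99.54% of accepted matches were correct. The settings of the match were chosen after the data had been seen. Functions given for a gene without a symbol are those of the matched entry, and RPA numbers are names from the authors' spreadsheet.

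Total counts were 14127303 and 17853257 in LowS, 14545671 and 16189717 in LowS_MTEtOH, 17225763 and 18256011 in NoMo, 16913585 and 18649068 in NoMo_MTEtOH and 16949019 and 16414705 in PM. At that depth counting error was small beside the spread between replicates, whose chi-square per gene was between 10.6 (NoMo) and 300.1 (LowS_MTEtOH). rRNA made up 1.5% ± 0.357 of counts in LowS (SD, n = 2), 1.06% ± 0.261 in PM, 0.983% ± 0.279 in LowS_MTEtOH, 0.816% ± 0.196 in NoMo_MTEtOH and 0.573% ± 0.109 in NoMo.

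Counts were tested in R 4.3.3 with edgeR 4.0.16, by glmQLFit and glmQLFTest after TMM normalisation and filterByExpr, which kept 4976 genes and left out 4. All 10 libraries were fitted together with 1 coefficient per group and no covariate, so that the 5 groups share the estimate of the spread (common biological coefficient of variation 0.173, prior degrees of freedom 3.21). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 6 pairwise comparisons and the interaction of MT-EtOH and molybdenum follow the groups. CPM values use the TMM library sizes, with a prior count of 2 where they are on the log2 scale. The fit was tested on simulated data with 200 changed genes among 4976 in each of 5 runs of LowS against PM, where it recovered 6.9% of genes changed 1.5-fold, 60.3% of those changed 2-fold and 96.1% of those changed 4-fold, with a mean of 4.2 and a maximum of 6 false calls. In the data 2623 of the 4976 genes were called in that comparison, a far larger share, so these rates may not hold for it.

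The comparisons, the overlap against PM, the test, the 15 gene lists, the rule for naming genes and the alternatives were set before the data were examined. The rule takes, for each pairwise comparison, the 8 strongest rises and falls among called genes with at least 10 CPM in 1 group and no overlap between the libraries of the groups, 5 each way for the interaction, up to 3 members of each list with the smallest adjusted p, the nitrogenase superfamily, and the 5 strongest entries of each list of the authors. The 2 chromosome stretches and the stretch of ribosomal protein genes were chosen after their values were seen. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and 12 lists with at least 3 tested members gave 84 tests over 7 comparisons, adjusted together. List members were taken by gene symbol alone. The rule as set also takes members by product name, but the count table and the reference give none for these genes, and the functions in the authors' spreadsheet cover only genes that the authors picked on these samples, so adding those members was run as an alternative. With an estimated correlation none of the list calls held.

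The overlaps that do not involve PM in both comparisons were added with the data in hand. Overlaps of calls were set beside the overlap of independent lists and beside 20 simulations of unchanged groups. With no gene changed few genes are called in these simulations, so their overlap of calls is almost empty by construction. The alternatives were DESeq2 size factors and upper-quartile scaling, no filter on low counts, the DESeq2 1.42.0 Wald test, only the groups compared in the fit, a fold minimum of 2, non-coding genes left out, the replicate number as a block, and each library left out in turn (10 fits). For lists they were an estimated correlation, the fry test, the block and DESeq2 size factors. 5 were added after seeing the data: both LowS_MTEtOH libraries left out, the 10 most abundant genes of every library left out, list members by the authors' function, and, for the overlaps with shared libraries, each PM library or each LowS library used in 1 of the 2 comparisons. A change of sign was counted as a reversal only where 1 of the values passed the test.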

Results

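RNA was sequenced from wild-type Rhodopseudomonas palustris CGA009, a purple bacterium that can live by photosynthesis, grown without oxygen on 10 mM malate. The 10 libraries fall into 5 groups of 2. PM is the full-sulfate medium, and LowS is the low-sulfate medium, with under 200 µM sulfate. LowS_MTEtOH is the low-sulfate medium with 1 mM MT-EtOH, 2-(methylthio)ethanol, an organic sulfur compound given as sulfur source. NoMo and NoMo_MTEtOH are low-sulfate medium made without molybdenum, without and with 1 mM MT-EtOH. The 10 most abundant genes took 26.0% ± 1.63 (SD, n = 2) of the counts in LowS_MTEtOH and 23.6% ± 1.34 in PM, against 15.6% ± 0.0707 in LowS and 15.6% ± 0.849 in NoMo_MTEtOH. Across genes, which are not independent replicates, the log2 CPM of the replicate libraries correlated at r = 0.955 in LowS_MTEtOH and between 0.992 and 0.997 in the other 4 groups. Levels below are counts scaled to library size (CPM), mean ± SD with n = 2 per group, and log2 fold changes stand with their standard error (SE). Where a gene is named for the size of its change, the libraries of the groups compared did not overlap, so its direction held in each of the 4 libraries. No label says that the replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical.

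The comparison of LowS with PM asked what the shortage of sulfate changed. The gene that rose most was TX73_RS07340, matched to the authors' entry RPA1430 and annotated by them as a MetQ/NlpA family substrate-binding protein of an ABC transporter. It went from 26.6 ± 1.48 CPM in PM to 14900 ± 2610 CPM in LowS. That is a 560-fold rise (log2 fold change 9.13 ± 0.24 SE, edgeR adjusted p = 2.78e-07). TX73_RS13505 (RPA2608), a substrate-binding protein for aliphatic sulfonates, rose 206-fold, from 66.4 ± 0.769 to 13700 ± 586 CPM (log2 7.68 ± 0.47, edgeR adjusted p = 8.36e-06). ssuD, the flavin-dependent monooxygenase that frees sulfite from alkanesulfonates, rose 62.5-fold, from 51 ± 1.1 to 3190 ± 211 CPM (log2 5.97 ± 0.20, edgeR adjusted p = 3.75e-07). The genes that fell most were those of anaerobic benzoate breakdown. bcrA, a subunit of the benzoyl-CoA reductase that opens the way to breaking the aromatic ring, fell 509-fold, from 3160 ± 1350 to 6.18 ± 1.1 CPM (log2 -8.99 ± 0.38, edgeR adjusted p = 1.06e-06).

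Several genes that the authors annotate as nitrogenase proteins were among the strongest rises. TX73_RS12140 (RPA2348), annotated as a nitrogenase molybdenum-iron protein alpha subunit and lying at 2660882 to 2662417 on the chromosome, rose 125-fold, from 14.2 ± 0.678 to 1770 ± 472 CPM (log2 6.96 ± 0.28, edgeR adjusted p = 8.13e-07). TX73_RS13650 (RPA2636), with the same annotation and at 2998779 to 3000287, rose 123-fold, from 17.9 ± 0.385 to 2190 ± 268 CPM (log2 6.94 ± 0.29, edgeR adjusted p = 8.96e-07). TX73_RS12215 (RPA2363), again with that annotation and at 2677747 to 2679252, rose 36.9-fold, from 14.3 ± 1.81 to 527 ± 69.6 CPM (log2 5.20 ± 0.55, edgeR adjusted p = 0.000162). TX73_RS13550 (RPA2617), annotated as a vanadium nitrogenase, rose 23.7-fold (log2 4.57 ± 0.17, edgeR adjusted p = 4.96e-07), and TX73_RS12175 (RPA2355), annotated as NifB, rose 177-fold (log2 7.47 ± 0.25, edgeR adjusted p = 3.71e-07). Of the structural genes of the molybdenum nitrogenase, nifD and nifK did not pass the test, with log2 fold changes of 0.13 ± 0.16 and -0.21 ± 0.16 (edgeR adjusted p = 0.512 and 0.292). The nifH copy beside them, TX73_RS23995, was called higher at 0.61 ± 0.21 (edgeR adjusted p = 0.0368). That call was lost without LowS replicate 2 (0.33), NoMo replicate 2 or 3 (0.61 each), PM replicate 1 (0.71) or PM replicate 3 (0.50). The labels do not name the genes of the reductase homologs that the series title speaks of, and no gene is assigned to that role here.

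**Figure D1:**
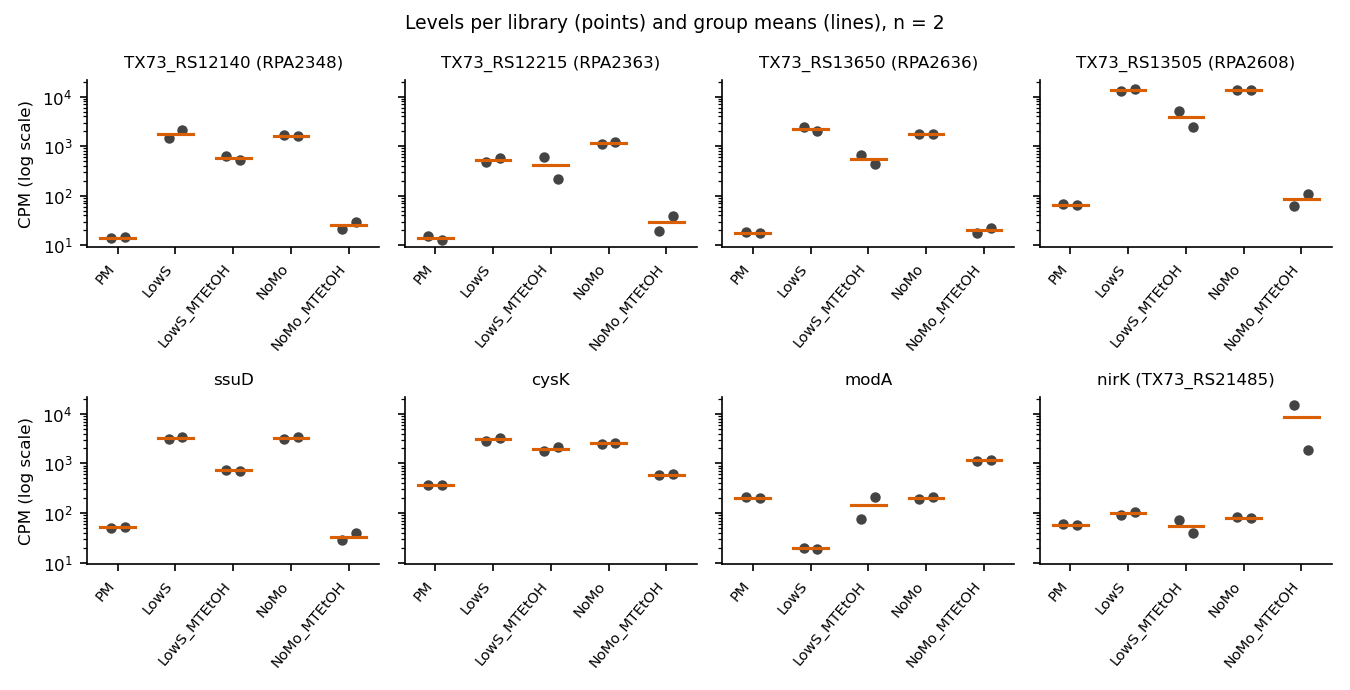
Levels of 8 genes in CPM on a log axis, 1 point per library and a line at each group's mean (n = 2). TX73_RS12140 (RPA2348) stood at 1770 CPM in LowS and 1640 CPM in NoMo, against 14.2 CPM in PM and 25.5 CPM in NoMo_MTEtOH, while modA was highest in NoMo_MTEtOH at 1160 CPM.

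These genes sat in 2 stretches of the chromosome, chosen after their values were seen. All 21 tested genes from TX73_RS12125 to TX73_RS12225 (2657016 to 2681756) rose in LowS, with a median log2 fold change of 5.72 and a range from 3.63 to 7.47. All 33 genes from TX73_RS13495 to TX73_RS13655 (2965554 to 3001681), which include ssuC and ssuD, rose as well, with a median of 5.88 and a range from 0.79 to 7.83. The first stretch also holds TX73_RS12180 (RPA2356), annotated as a cystathionine beta-synthase (log2 7.11 ± 0.23, edgeR adjusted p = 3.02e-07), and TX73_RS12200 (RPA2360), an ATP-binding protein of a methionine ABC transporter (log2 6.00 ± 0.24, edgeR adjusted p = 7.8e-07).

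**Figure D2:**
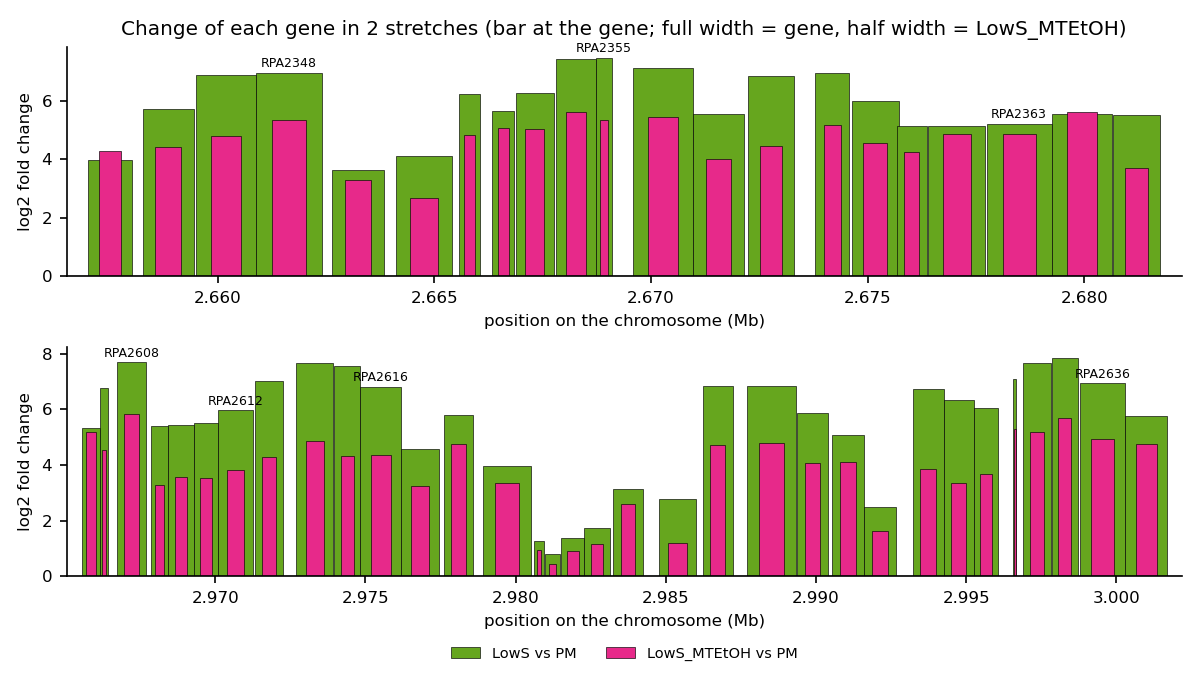
Log2 fold change against PM of each gene in the 2 stretches, drawn at its position in Mb, with the wide bars for LowS and the narrow bars for LowS_MTEtOH. All 21 genes of the upper stretch and all 33 of the lower stretch were higher than in PM in both comparisons, with medians of 5.72 and 5.88 in LowS and of 4.83 and 4.09 in LowS_MTEtOH.

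Among the gene lists fixed for the study, all 8 tested genes of sulfate uptake and assimilation rose in LowS, 8 also when adjusted over the list alone, with a median log2 fold change of 2.33 (camera adjusted p = 5.8e-05, and adjusted p = 0.214 with an estimated correlation). cysK, which makes cysteine from sulfide, rose 8.35-fold to 3040 ± 265 CPM (log2 3.06 ± 0.15, edgeR adjusted p = 3e-06), and cysC, a kinase of sulfate activation, rose 5.39-fold. One member, cysS, serves in translation as the ligase that charges tRNA with cysteine. Both tested genes of organosulfur uptake and use, ssuC and ssuD, rose, 2 also when adjusted over the list alone, with a median of 5.74 and too few members for a list test. Of 4 genes of Fe-S cluster assembly 3 rose, 3 also when adjusted over the list alone, among them sufD at log2 2.87 ± 0.15 (median 2.31, camera adjusted p = 0.0146, and adjusted p = 0.587 with an estimated correlation). All 5 tested hyp genes of hydrogenase maturation fell, 5 also when adjusted over the list alone, among them hypA at log2 -4.42 ± 0.36 (median -4.17, camera adjusted p = 0.00166, and adjusted p = 0.587 with an estimated correlation). The hydrogenase call ended, at camera adjusted p = 0.192, once 4 genes that the authors annotate as hydrogenase were added, which is no independent test because the authors drew them from these samples. Of the 4 genes 3 rose, and these (TX73_RS12135, TX73_RS12220 and TX73_RS13655) lie in the 2 stretches, beside genes annotated as nitrogenase alpha subunits. The 1 that fell, TX73_RS05005, annotated as a nickel-dependent hydrogenase large subunit, lies beside the hyp genes. Of the 19 members of the nitrogenase superfamily named by symbol, 11 rose and 0 fell, 11 and 0 adjusted over the list alone (median 0.61, camera adjusted p = 0.00546, and adjusted p = 0.587 with an estimated correlation). They include bchY, of the chlorophyllide reductase, and bchB, of the protochlorophyllide reductase, enzymes of pigment synthesis, at log2 1.41 ± 0.19 and 1.07 ± 0.13. Of 51 ribosomal protein genes 26 rose and 6 fell, 28 and 6 adjusted over the list alone (median 0.53, camera adjusted p = 0.00604, and adjusted p = 0.743 with an estimated correlation). Of the 26 that rose 20 lay in the run from rplQ to rpsJ described below, where 1 fell, and elsewhere 6 rose and 5 fell.

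The other lists did not pass the camera test in LowS against PM. Of 9 genes of molybdenum uptake and cofactor synthesis, 2 rose and 5 fell, counts that were the same adjusted over the list alone (median -0.46, camera adjusted p = 0.158). The molybdate transporter genes modA, modB and modC were among those that fell, modA from 205 ± 9.37 to 19.4 ± 0.647 CPM (log2 -3.40 ± 0.41, edgeR adjusted p = 0.000294). Of 30 genes of the photosystem and pigment synthesis, 11 rose and 11 fell, 12 and 11 adjusted over the list alone (camera adjusted p = 0.835, median 0.11 but mean -0.44). Antenna genes with the reference symbol pufB were among those that fell, TX73_RS22235 from 7500 ± 579 to 590 ± 92.4 CPM (log2 -3.67 ± 0.25), with reads shared between the copies uncertain. TX73_RS22235 lies apart from the pufB gene beside pufA, pufL and pufM (TX73_RS07845), so the shared symbol may not mean the same antenna. Of 11 methionine genes 7 rose and 2 fell, as they did adjusted over the list alone (median 0.57, camera adjusted p = 0.0696). The 11 include metG, by its symbol the ligase that charges tRNA with methionine. Of 29 genes for chaperones and oxidative stress 14 rose and 4 fell, unchanged adjusted over the list alone (median 0.34, camera adjusted p = 0.223). The list of flagella and chemotaxis held 27 flagellar genes and no chemotaxis gene by symbol. Of these 27 genes 9 rose and 5 fell, unchanged adjusted over the list alone (median -0.01, mean 0.15, camera adjusted p = 0.567). Another 13 members by the authors' function, chemotaxis genes among them, had 2 higher and 4 lower. Those 13 had 0 higher and 13 lower in LowS_MTEtOH against LowS, and 0 and 12 in NoMo against LowS. The authors drew them from these samples, so they are no independent test. Of 16 genes of nitrogenase regulation and nitrogen starvation 5 rose and 3 fell, 4 and 3 adjusted over the list alone (median 0.39, camera adjusted p = 0.733). Of 12 genes of iron uptake 3 rose and 1 fell, 2 and 0 adjusted over the list alone (median 0.35, camera adjusted p = 0.437). The Calvin cycle list, with cbbX alone at log2 1.67 ± 0.22, and the ATP synthase list were too small to test. The ATP synthase list has 2 members at a median of -0.08, of which 1 fell, 1 also adjusted over the list alone. In all, 2623 of 4976 tested genes changed in LowS, 1304 higher and 1319 lower, and 1257 of them by at least 2-fold (581 higher, 676 lower).

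**Figure D3:**
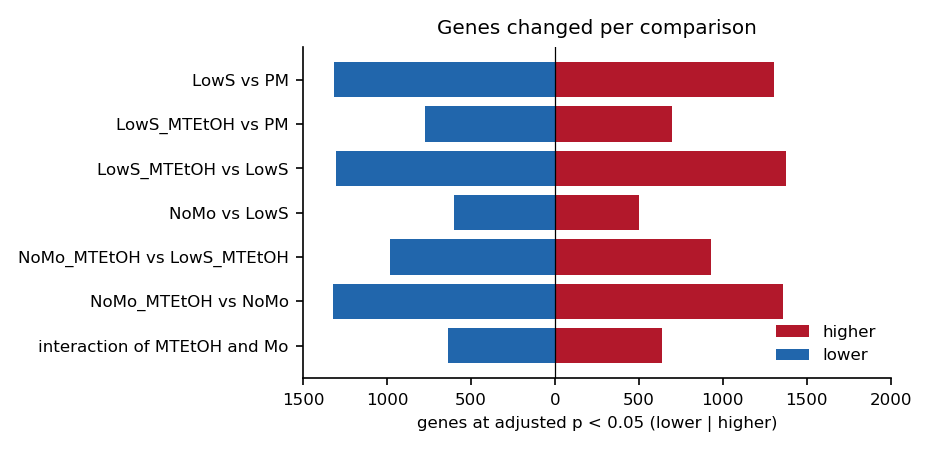
Number of genes past the threshold (edgeR adjusted p under 0.05) in each comparison, with bars to the right for genes higher and to the left for genes lower in the first group named. LowS_MTEtOH against LowS, with 1379 higher and 1307 lower, and NoMo_MTEtOH against NoMo, with 1357 and 1325, had about equally many. NoMo against LowS had the fewest in this fit, with 502 higher and 601 lower. With only the groups compared in the fit the order was different. LowS_MTEtOH against LowS then had 1324 genes and NoMo_MTEtOH against NoMo 3731.

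In the authors' deposited table for LowS against PM, 190 entries are listed as up and 246 as down, none with a log2 fold change under 2.0 in size. The 5 entries highest in the authors' deposited table are RPA1430 at 9.14, a hypothetical protein with no RPA number at 7.98, RPA2635 at 7.84, RPA2608 at 7.78 and RPA2614 at 7.71. The 5 lowest in the authors' deposited table are RPA0659 at -9.09, RPA0658 at -8.71, RPA0654 at -8.46, RPA0660 at -8.25 and RPA0655 at -7.76, which lie in the bcr and bad region of benzoate breakdown. For LowS_MTEtOH against PM the authors' deposited table gives 294 entries up and 362 down, with a smaller limit of 1.0 on the size of the change. Those of the authors' deposited table are led by RPA2608 at 5.94, RPA2635 at 5.7, RPA2364 at 5.65, RPA2354 at 5.64 and RPA2356 at 5.46. Its lowest entries in the authors' deposited table are RPA0659 at -7.76, RPA0658 at -7.66, RPA0660 at -7.59, RPA0657 at -6.57 and RPA0661 at -5.52. Entries that could be matched to the count table were called in the same direction here for 151 of 152 and 195 of 195 in LowS, and for 219 of 233 and 261 of 272 in LowS_MTEtOH. The 1 matched entry called higher here in a list of lowered genes, RPA0035, named after its value was seen, also stands at 1.33 in the authors' deposited table. The authors' deposited table was drawn from these same libraries, so these counts are no independent evidence.

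The comparison of LowS_MTEtOH with PM asked how cells given the organic sulfur compound differed from cells with full sulfate. The same 2 stretches stood high, with all 21 genes (median log2 4.83) and all 33 genes (median 4.09) raised. TX73_RS12140 (RPA2348) rose to 573 ± 83.2 CPM (log2 5.33 ± 0.26, edgeR adjusted p = 4.76e-06) and TX73_RS13650 (RPA2636) to 551 ± 174 CPM (log2 4.95 ± 0.26, edgeR adjusted p = 7.04e-06). The sulfonate-binding gene TX73_RS13505 (RPA2608) rose to 3790 ± 1900 CPM (log2 5.84 ± 0.43, edgeR adjusted p = 3.74e-05). The genes of benzoate breakdown were again the lowest, with bcrA at 15.1 ± 0.304 CPM (log2 -7.71 ± 0.36, edgeR adjusted p = 3.86e-06) and the ligase gene TX73_RS03425 (RPA0661) at log2 -5.48 ± 0.48. A porin gene, TX73_RS02785 (RPA0538), fell from 4100 ± 284 to 137 ± 32.2 CPM (log2 -4.91 ± 0.23, edgeR adjusted p = 4.13e-06).

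Of 51 ribosomal protein genes 30 rose and 0 fell in LowS_MTEtOH, 30 and 1 adjusted over the list alone, among them rplO from 65.2 ± 6.52 to 313 ± 22.4 CPM (median 0.70, camera adjusted p = 6.22e-12, and adjusted p = 0.389 with an estimated correlation). Of 8 sulfate genes 6 rose, 6 also adjusted over the list alone, with cysK at log2 2.43 ± 0.15 (median 0.91, camera adjusted p = 0.00264, and adjusted p = 0.228 with an estimated correlation). All 5 hyp genes fell, 5 also adjusted over the list alone (median -2.56, camera adjusted p = 0.0011, and adjusted p = 0.587 with an estimated correlation). This call ended at camera adjusted p = 0.222 when the authors' 4 hydrogenase entries, drawn from these samples, were added. Again the 3 in the 2 stretches rose and the 1 beside the hyp genes fell. Of 29 genes for chaperones and oxidative stress 10 rose and 0 fell, 10 and 0 adjusted over the list alone (median 0.31, camera adjusted p = 0.00191, and adjusted p = 0.587 with an estimated correlation). The groL genes TX73_RS05855 (log2 1.16 ± 0.18) and TX73_RS11165 (2.29-fold), coding for the chaperonin GroEL, were among them. Both of these calls were lost when only the PM and LowS_MTEtOH libraries were fitted. In all 1473 genes changed, 698 higher and 775 lower, and 616 of them by at least 2-fold. The count was 2313 without LowS_MTEtOH replicate 3, 963 without PM replicate 1, 778 without PM replicate 3 and 360 when only the libraries of PM and LowS_MTEtOH were fitted.

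LowS and LowS_MTEtOH moved the same way from PM for 749 genes, 331 higher and 418 lower. Lists that were independent of each other would share 183 and 205 genes. In 20 simulations of unchanged groups against the same PM libraries the mean overlap was 0 with a maximum of 1. No gene was changed in them, so that overlap was almost empty by construction and is no measure for the 749 genes. The covariance of the log2 fold changes was 0.795, against 0.0357 in the simulations, with r = 0.649 against 0.493 and the same sign in 60.5% of genes against 66.3%. Both comparisons share the 2 PM libraries, so part of the excess may come from them. With each PM library in 1 of the 2 comparisons the overlap was 440 and 425, where independent lists would give 91 and 110, and 59 and 98. The covariance was then 0.754 and 0.79. The overlap was 1410 without LowS_MTEtOH replicate 3, 494 without PM replicate 1, 438 without PM replicate 3, 367 with a fold minimum of 2 and 276 when only the groups compared were fitted.

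The comparison of LowS_MTEtOH with LowS asked what the addition of MT-EtOH changed where molybdenum was present. The strongest rise was that of TX73_RS13490, which lies just beside the second stretch and went from 209 ± 109 to 27800 ± 7640 CPM (log2 7.06 ± 0.43, edgeR adjusted p = 2.53e-05). adh, annotated by the authors as an aldehyde dehydrogenase, rose from 20.8 ± 9.68 to 1450 ± 1240 CPM (log2 6.12 ± 0.69, edgeR adjusted p = 0.000252). Antenna genes with the reference symbol pufB rose, TX73_RS13745 from 2250 ± 760 to 37200 ± 12500 CPM (log2 4.05 ± 0.33) and TX73_RS22235 from 590 ± 92.4 to 10100 ± 3000 CPM (log2 4.10 ± 0.25), with edgeR adjusted p = 6.6e-05 and 2.53e-05 and reads shared between copies uncertain. Both lie apart from the pufB gene beside pufA, pufL and pufM. 2 other pufB copies had replicates far apart, and TX73_RS15585, at log2 5.06 ± 1.07, stood at 2.00 without LowS_MTEtOH replicate 3, while TX73_RS15605, at 5.48 ± 1.14, stood at 2.14. The genes that rose under low sulfate stood lower, with TX73_RS07340 (RPA1430) at 633 ± 60.3 CPM (log2 -4.56 ± 0.20, edgeR adjusted p = 1.4e-05), ssuD at 721 ± 22.9 CPM (log2 -2.15 ± 0.17) and TX73_RS12140 (RPA2348) at log2 -1.63 ± 0.22 (edgeR adjusted p = 0.000623). Of the 2 stretches 15 of 21 and 28 of 33 genes fell, with medians of -1.43 and -1.90. TX73_RS12215 (RPA2363) did not pass the test, at log2 -0.35 ± 0.46 (edgeR adjusted p = 0.545) with replicates at 614 and 214 CPM. Without LowS_MTEtOH replicate 2 it was called lower, at -1.30.

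All 8 sulfate genes fell with MT-EtOH, 8 also adjusted over the list alone, with cysC at log2 -1.53 ± 0.13 (median -1.17, camera adjusted p = 0.00132, and adjusted p = 0.227 with an estimated correlation). The largest fall among them was that of cysS, the tRNA ligase, at -2.14 ± 0.25. 3 of 4 genes of Fe-S cluster assembly fell, 3 also adjusted over the list alone, with sufD at log2 -2.61 ± 0.15 (median -2.03, camera adjusted p = 0.0305, and adjusted p = 0.587 with an estimated correlation). Of 19 nitrogenase superfamily genes 10 fell and 1 rose, as they did adjusted over the list alone (median -0.47, camera adjusted p = 0.0271, and adjusted p = 0.587 with an estimated correlation). Of 51 ribosomal protein genes 25 rose and 4 fell, 26 and 5 adjusted over the list alone (median 0.54, camera adjusted p = 0.00282, and adjusted p = 0.712 with an estimated correlation). The molybdenum list did not pass (6 of 9 higher, 6 also adjusted over the list alone, median 0.59, camera adjusted p = 0.0738), although modA rose from 19.4 ± 0.647 to 142 ± 93.1 CPM (log2 2.88 ± 0.40, edgeR adjusted p = 0.000649). glnA, glutamine synthetase, rose from 280 ± 16.8 to 1230 ± 98.4 CPM (log2 2.13 ± 0.14, edgeR adjusted p = 3.17e-05), but its list of nitrogenase regulation and nitrogen starvation did not pass, with 2 of 16 higher and 6 lower, unchanged adjusted over the list alone (median -0.49, camera adjusted p = 0.558). Beside the pufB copies that rose, the list of the photosystem and pigment synthesis did not pass either, with 9 of 30 higher and 15 lower, 9 and 16 adjusted over the list alone (median -0.41, mean 0.31, camera adjusted p = 0.349). In all 2686 genes changed, 1379 higher and 1307 lower, and 1244 of them by at least 2-fold. When only the LowS and LowS_MTEtOH libraries were fitted the count was 1324.

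A change in LowS against PM was followed by a change the other way in LowS_MTEtOH against LowS for 1850 genes, 921 of them raised and 929 lowered by low sulfate. Independent lists would give 343 and 366. The simulations, with no gene changed, gave a mean of 0 and a maximum of 1 by construction. The covariance of the log2 fold changes was -0.976, against -0.0373 in the simulations, with r = -0.723 against -0.51. The LowS libraries enter both comparisons with opposite sign, so part of the excess may come from them. With each LowS library in 1 of the 2 comparisons the overlap was 1219 and 1229, where independent lists would give 198 and 192, and 224 and 205. The covariance was then -0.968 and -0.945. The overlap was 1205 without LowS replicate 2, 1091 when only the groups compared were fitted and 748 with a fold minimum of 2.

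The comparison of NoMo with LowS asked what the absence of molybdenum changed where no MT-EtOH was given. The genes that rose most were those of the molybdate transporter and its neighbours. modA, its substrate-binding protein, rose from 19.4 ± 0.647 to 201 ± 11.8 CPM (log2 3.38 ± 0.41, edgeR adjusted p = 0.00137), modB by log2 3.37 ± 0.34 and modC by log2 2.91 ± 0.24. As given above, modA was lower in LowS than in PM, and its NoMo level was near that of PM. TX73_RS24510 (RPA4718), annotated as a TOBE domain protein, rose from 18 ± 0.437 to 290 ± 33.1 CPM (log2 4.01 ± 0.36, edgeR adjusted p = 0.000374). The strongest falls were in a run of neighbouring genes from TX73_RS06290 to TX73_RS06310, with TX73_RS06300 from 296 ± 3.53 to 20.1 ± 1.21 CPM (log2 -3.88 ± 0.14, edgeR adjusted p = 1.17e-05). The genes raised by low sulfate stood near their LowS level, with a median log2 difference of -0.07 over the 21 genes of the first stretch (1 fell) and 0 over the 33 of the second (3 rose, 1 fell). TX73_RS12140 (RPA2348) did not pass the test, at log2 -0.11 ± 0.22 (edgeR adjusted p = 0.747), and neither did TX73_RS13650 (RPA2636), at -0.31 ± 0.22. TX73_RS12215 (RPA2363), at 1.16 ± 0.46 (edgeR adjusted p = 0.109), was called higher without LowS_MTEtOH replicate 2, replicate 3 or both (1.16 each), with the DESeq2 Wald test, and with the LowS and NoMo libraries alone (1.14 each).

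Of 30 genes of the photosystem and pigment synthesis 19 fell and 0 rose without molybdenum, 20 and 0 adjusted over the list alone (median -1.06, camera adjusted p = 5.95e-11, and adjusted p = 0.227 with an estimated correlation). puhB, of the reaction centre operon, fell from 7090 ± 1220 to 1280 ± 130 CPM (log2 -2.47 ± 0.18), and bchJ, of bacteriochlorophyll synthesis, fell by 1.82 on the log2 scale (SE 0.12), with edgeR adjusted p = 0.000165 and 0.000126. Of 9 genes of molybdenum uptake and cofactor synthesis 4 rose, 4 also adjusted over the list alone (median 0.35, camera adjusted p = 0.023, and adjusted p = 0.385 with an estimated correlation). Of 11 methionine genes 5 fell and 1 rose, as they did adjusted over the list alone, among them metK, which makes S-adenosylmethionine, at log2 -1.06 ± 0.15 (median -0.19, camera adjusted p = 0.0486, and adjusted p = 0.587 with an estimated correlation). That call ended at adjusted p = 0.0583 with the members by the authors' function added. metG, the tRNA ligase, is among the 11. Of the 8 sulfate genes 0 rose and 1 fell, unchanged adjusted over the list alone (camera adjusted p = 0.835). Their median was 0.01, against 0.09 with upper-quartile scaling and -0.01 with DESeq2 size factors. In all 1103 genes changed, 502 higher and 601 lower, and 374 of them by at least 2-fold. Of these 374 genes 109 were higher and 265 lower. Among all changed genes the share that was higher was 45.5%, and over the alternatives it ran from 26.7% without LowS replicate 1 to 57.6% with upper-quartile scaling. The count was 401 without LowS replicate 1, 643 without LowS replicate 2, 300 without NoMo replicate 2 and 302 without NoMo replicate 3. It was 2201 and 2199 without LowS_MTEtOH replicate 2 and replicate 3, neither of which is in the comparison, and 2184 when only the LowS and NoMo libraries were fitted.

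The comparison of NoMo_MTEtOH with LowS_MTEtOH asked what the absence of molybdenum changed in cells given MT-EtOH. The genes of the 2 stretches were far lower, with 20 of the 21 genes of the first (median log2 -4.40) and 32 of the 33 of the second (median -4.12) past the test. TX73_RS12140 (RPA2348) fell from 573 ± 83.2 to 25.5 ± 5.4 CPM (log2 -4.49 ± 0.25, edgeR adjusted p = 1.08e-05). TX73_RS13650 (RPA2636) fell from 551 ± 174 to 20.1 ± 3.37 CPM (log2 -4.78 ± 0.26, edgeR adjusted p = 9.38e-06) and TX73_RS12215 (RPA2363) by 3.83 on the log2 scale (SE 0.51, edgeR adjusted p = 0.00106). ssuD fell from 721 ± 22.9 to 33.3 ± 7.36 CPM (log2 -4.44 ± 0.19, edgeR adjusted p = 3.81e-06). The strongest rises had replicates far apart. nirK (TX73_RS21485), the gene of a copper nitrite reductase, went from 54.8 ± 22.6 to 8530 ± 9430 CPM, with 15200 CPM in replicate 1 and 1860 CPM in replicate 2 (log2 7.28 ± 0.97, edgeR adjusted p = 0.00104), and stood at log2 5.07 without replicate 1. TX73_RS07475 went from 5.95 ± 1.02 to 980 ± 1230 CPM (log2 7.36 ± 1.24, edgeR adjusted p = 0.0029), stood at 4.16 without NoMo_MTEtOH replicate 1, and lost its call when only the groups compared were fitted. The molybdate transporter genes rose, with modA from 142 ± 93.1 to 1160 ± 21.9 CPM (log2 3.02 ± 0.40, edgeR adjusted p = 0.000966).

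The GroEL gene TX73_RS11165 rose from 157 ± 5.05 to 1230 ± 67 CPM without molybdenum (log2 2.96 ± 0.19, edgeR adjusted p = 2.87e-05), but the list of chaperones and oxidative stress went both ways, with 6 of 29 higher and 6 lower, 7 and 6 adjusted over the list alone (median 0.07, camera adjusted p = 0.604). Of 8 sulfate genes 5 fell and 1 rose, as they did adjusted over the list alone, with cysK from 1970 ± 273 to 591 ± 20.7 CPM (median -0.81, camera adjusted p = 0.0137, and adjusted p = 0.352 with an estimated correlation). No other list passed the camera test in this comparison, and the molybdenum list had 5 of 9 higher and 2 lower, unchanged adjusted over the list alone (median 0.46, camera adjusted p = 0.193). In all 1909 genes changed, 928 higher and 981 lower, and 737 of them by at least 2-fold. The count was 885 without NoMo_MTEtOH replicate 1, 1052 without NoMo_MTEtOH replicate 2 and 412 when only the LowS_MTEtOH and NoMo_MTEtOH libraries were fitted.

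The comparison of NoMo_MTEtOH with NoMo asked what MT-EtOH changed where molybdenum was absent. All 21 genes of the first stretch and all 33 of the second fell, with median log2 fold changes of -5.39 and -6.42. TX73_RS12140 (RPA2348) fell from 1640 ± 14.5 to 25.5 ± 5.4 CPM (log2 -6.00 ± 0.27, edgeR adjusted p = 1.89e-06). TX73_RS13650 (RPA2636) fell from 1760 ± 22.7 to 20.1 ± 3.37 CPM (log2 -6.46 ± 0.28, edgeR adjusted p = 1.62e-06) and TX73_RS12215 (RPA2363) from 1180 ± 65.1 to 29.1 ± 13.4 CPM (log2 -5.34 ± 0.55, edgeR adjusted p = 0.000134). The radical SAM gene TX73_RS13535 (RPA2614) fell by 8.07 on the log2 scale (SE 0.23, edgeR adjusted p = 3e-07) and ssuD from 3230 ± 157 to 33.3 ± 7.36 CPM (log2 -6.60 ± 0.21, edgeR adjusted p = 3.33e-07). The GroEL gene TX73_RS11165 rose from 46.7 ± 1.76 to 1230 ± 67 CPM (log2 4.72 ± 0.21, edgeR adjusted p = 1.74e-06). Rises were also seen for modA, from 201 ± 11.8 to 1160 ± 21.9 CPM (log2 2.52 ± 0.39, edgeR adjusted p = 0.000965), and for glnA, from 236 ± 7.82 to 1120 ± 41.4 CPM (log2 2.24 ± 0.14, edgeR adjusted p = 1.12e-05). nirK rose from 80.2 ± 1.03 to 8530 ± 9430 CPM (log2 6.73 ± 0.94, edgeR adjusted p = 0.000621), with the unequal replicates given above.

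All 8 sulfate genes fell here as well, 8 also adjusted over the list alone, with cysT, a permease subunit of the sulfate transporter, at log2 -2.14 ± 0.14 (median -2.11, camera adjusted p = 9.24e-05, and adjusted p = 0.214 with an estimated correlation). 3 of 4 genes of Fe-S cluster assembly fell, 3 also adjusted over the list alone, with sufD at log2 -2.69 ± 0.15 (median -1.83, camera adjusted p = 0.0305, and adjusted p = 0.587 with an estimated correlation). Of 19 nitrogenase superfamily genes 11 fell and 1 rose, 12 and 2 adjusted over the list alone (median -0.51, camera adjusted p = 0.0304, and adjusted p = 0.587 with an estimated correlation). Of 30 photosystem and pigment genes 14 rose and 2 fell, as they did adjusted over the list alone (median 0.47, camera adjusted p = 0.0277, and adjusted p = 0.587 with an estimated correlation). Among 51 ribosomal protein genes 27 rose and 12 fell, unchanged adjusted over the list alone (median 0.55, camera adjusted p = 0.0277, and adjusted p = 0.81 with an estimated correlation). In the run from rplQ to rpsJ described below 18 rose and 0 fell, while elsewhere 9 rose and 12 fell. The lists that hold the GroEL gene, modA and glnA did not pass. Chaperones and oxidative stress had 8 of 29 higher and 11 lower (median -0.20, camera adjusted p = 0.835), molybdenum 4 of 9 higher and 1 lower (median 0.48, camera adjusted p = 0.309), and nitrogenase regulation and nitrogen starvation 2 of 16 higher and 4 lower (median -0.32, camera adjusted p = 0.721), all unchanged adjusted over the list alone. In all 2682 genes changed, 1357 higher and 1325 lower, and 1229 of them by at least 2-fold, with 1715 changed without NoMo replicate 2.

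MT-EtOH moved 1535 genes the same way with and without molybdenum, 743 up and 792 down, where independent lists would share 376 and 348. These comparisons share no libraries. The simulations, with no gene changed, gave a mean overlap of 0 with a maximum of 0 by construction. Across genes the log2 fold changes correlated at r = 0.573, against -0.006 in the simulations, and 70% of the 4976 tested genes had the same sign. The overlap was 617 with a fold minimum of 2.

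The interaction asked whether the response to MT-EtOH differed without molybdenum. In the first stretch 20 of 21 genes, and in the second 32 of 33, passed with a lower response to MT-EtOH where molybdenum was absent (median differences -4.33 and -4.07). The exceptions, named after their values were seen, were TX73_RS12150 and TX73_RS13590, which did not pass. The difference was log2 -4.38 ± 0.32 for TX73_RS12140 (RPA2348), -4.47 ± 0.33 for TX73_RS13650 (RPA2636) and -4.99 ± 0.69 for TX73_RS12215 (RPA2363) (edgeR adjusted p = 9.05e-05, 9.05e-05 and 0.00235). For ssuD the difference was -4.46 ± 0.24 (edgeR adjusted p = 2.94e-05), and for cysK it was -1.49 ± 0.20 (edgeR adjusted p = 0.00231). nirK (TX73_RS21485) had the difference 7.57 ± 1.17 and the GroEL gene TX73_RS11165 had 2.86 ± 0.26 (edgeR adjusted p = 0.00361 and 0.000316), while the list of chaperones and oxidative stress did not pass, with 4 of 29 higher and 5 lower, 4 and 6 adjusted over the list alone (median -0.13, camera adjusted p = 0.757). bchJ, of bacteriochlorophyll synthesis, had 2.42 ± 0.17 (edgeR adjusted p = 6.87e-05).

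The photosystem list differed in its response, with 14 of 30 genes higher and 5 lower in the interaction, 17 and 5 adjusted over the list alone (median 0.85, camera adjusted p = 0.00132, and adjusted p = 0.587 with an estimated correlation). Of 12 genes of iron uptake 3 were higher, 3 also adjusted over the list alone, among them exbD (TX73_RS17995) at 1.72 ± 0.25 (median 1.14, camera adjusted p = 0.023, and adjusted p = 0.712 with an estimated correlation). The fry test did not make this call (adjusted p = 0.0513). Of 8 sulfate genes 5 were lower, 6 adjusted over the list alone (median -0.93, camera adjusted p = 0.0277, and adjusted p = 0.389 with an estimated correlation). In all 1272 genes passed the interaction test, 635 with a positive and 637 with a negative difference, and 768 of them had a difference of at least 2-fold. The count was 754 and 840 without LowS replicate 1 and 2, and 2277 and 2127 without LowS_MTEtOH replicate 2 and 3. It was 459 and 627 without NoMo replicate 2 and 3, and 558 and 654 without NoMo_MTEtOH replicate 1 and 2.

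**Figure D4:**
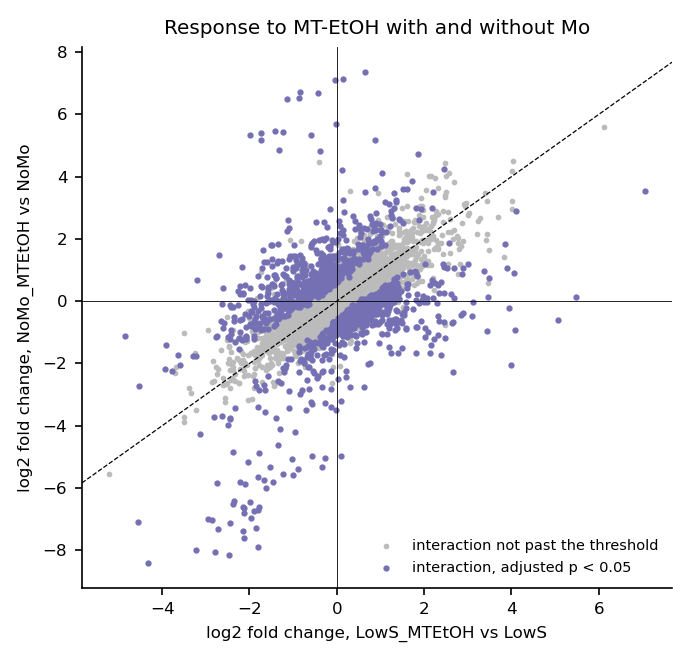
Log2 fold change of each of the 4976 tested genes with MT-EtOH, with molybdenum on the horizontal axis (LowS_MTEtOH against LowS) and without it on the vertical axis (NoMo_MTEtOH against NoMo), the dashed line marking equal change. The 1272 genes past the interaction test are coloured, and the cloud has r = 0.573.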

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

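All the tests of explanations in this part were chosen only after the results they weigh had been seen, and so were the floors of 3 and 5 on the log2 scale that define the groups of genes and the comparisons of NoMo and NoMo_MTEtOH with PM. The interaction test itself was planned.

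The response to MT-EtOH differed with molybdenum for 1272 genes, and this difference between groups singled out the genes and lists that follow. The differences on the log2 scale were 7.63 for TX73_RS10670, 7.57 for nirK (TX73_RS21485), 7.40 for TX73_RS21490, 7.31 for TX73_RS07640 and 7.15 for TX73_RS07645. On the other side they were -6.08 for TX73_RS13635, -6.05 for TX73_RS21860, -5.69 for TX73_RS13640 and -5.47 for TX73_RS12175. For the pufB copy TX73_RS15585 the difference was -5.67, and the call was lost without LowS replicate 1 (-5.98), LowS replicate 2 (-5.42), NoMo replicate 2 (-5.64), NoMo replicate 3 (-5.70), NoMo_MTEtOH replicate 1 (-5.60) or NoMo_MTEtOH replicate 2 (-5.79), and the value was -2.62 without LowS_MTEtOH replicate 3. The lists of the photosystem (camera adjusted p = 0.00132, median difference 0.85, 14 of 30 genes called higher and 5 lower), iron uptake (adjusted p = 0.023, median 1.14, 3 of 12 higher) and sulfate assimilation (adjusted p = 0.0277, median -0.93, 5 of 8 lower) differed as well. None of the 3 passed camera with an estimated correlation (adjusted p = 0.587, 0.712 and 0.389), while the fry test passed the photosystem (0.002) and sulfate (0.00194) lists but not iron uptake (0.0513).

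The first pattern is that genes raised under low sulfate stood near their PM level in NoMo_MTEtOH: over the 88 genes raised by at least 3 on the log2 scale in LowS, the median difference to PM was 5.27 in LowS, 3.53 in LowS_MTEtOH, 5.37 in NoMo and 0.73 in NoMo_MTEtOH. The values argue against sulfate in the molybdenum-free medium as such, since NoMo had the median of 5.37. They argue against molybdenum in the NoMo_MTEtOH cultures as the cause, since that would be the medium of LowS_MTEtOH, and against that group the median was -3.17 (quartiles -4.41 to -0.94, with 65 genes lower and 10 higher). A few genes taking most of the counts would not account for it either, since the shares of the 10 most abundant genes allow a shift of at most 0.22 in all other genes. Sulfate in the NoMo_MTEtOH cultures alone, another sulfur compound brought in with MT-EtOH, and an effect of molybdenum shortage on the use of MT-EtOH stay open and were not tested.

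The second pattern is the spread of the LowS_MTEtOH replicates, which correlated at r = 0.955 where the other groups' replicates correlated at 0.992 or more. If replicate 2 held RNA of a LowS culture beside that of a culture like replicate 3, 1 share of LowS RNA would have to account for all genes. Genes low in LowS and high in replicate 3 implied a median of 82.7% (quartiles 70.2 to 89.1, 42 genes). Genes high in LowS and low in replicate 3 allowed 12.4% (5.5 to 23.8, 60 genes). Both sets were chosen by replicate 3, taken as unmixed, so the values speak against that mix only. A wrong label within the series on replicate 2 or 3 is argued against by the highest correlation of either with a library of another group, 0.926, below that of the replicates with each other. A difference in growth stage or in the sulfur left at harvest may account for the spread, and the labels give nothing to test it with.

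The third pattern is a set of 15 genes, nirK among them, raised by at least 5 on the log2 scale in NoMo_MTEtOH, with replicate 1 from 3.36 to 24.01 times replicate 2. Without replicate 1, 100% of the 15 genes remained called, but the lone library left is then assumed to vary like the other groups. That fit leaves out the spread in question, so it cannot decide whether the calls rest on 1 library. In size, the rises were seen in replicate 2 as well, with log2 fold changes from 1.67 to 5.55 without replicate 1. Their size rests in part on replicate 1, since only 5 of the 15 genes then stood at 5 or more. If RNA of 1 other culture made up their level in both libraries, all of them would have about the same ratio of replicate 1 to replicate 2. The highest ratio was 7.1 times the lowest, which argues against that mix only. The ratios cannot decide on RNA of another culture in replicate 1 alone, since beside the genes' own level they could then differ. Unequal induction of these genes in the 2 samples is a further hypothesis, and its trigger was not tested.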

How the results depend on the processing

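The fit without both LowS_MTEtOH libraries, the removal of abundant genes, the list members by the authors' function and the division of shared libraries between comparisons were chosen only after the results had been seen, and the other alternatives were planned.

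No value of a named gene and no list test reversed under any alternative run. Counts of changed genes carry no sign and could not be counted as reversed, but the direction with more genes did change in some fits. With upper-quartile scaling NoMo against LowS went from 502 higher and 601 lower to 702 and 517. NoMo_MTEtOH against LowS_MTEtOH went from 928 and 981 to 984 and 917. With DESeq2 size factors 544 of the 545 values of named genes kept their direction and side of the threshold, with the DESeq2 Wald test 539, with no filter on low counts 545, with upper-quartile scaling 537, without non-coding genes 545, with only the groups compared 490, with the replicate block 501 and with the fold minimum 480. Leaving out 1 library took away between 2 and 38 of their calls and added 28 and 26 without LowS_MTEtOH replicate 2 and 3 and 2 without PM replicate 1, and the lone sample of a group is then assumed to vary like the other groups.

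Counts of changed genes ran, without each library in turn, from 1879 to 3294 for LowS against PM (2623 with all), from 778 to 2313 for LowS_MTEtOH against PM (1473), from 1973 to 3254 for LowS_MTEtOH against LowS (2686), from 300 to 2201 for NoMo against LowS (1103), from 885 to 2763 for NoMo_MTEtOH against LowS_MTEtOH (1909), from 1715 to 3381 for NoMo_MTEtOH against NoMo (2682) and from 459 to 2277 for the interaction (1272). The overlap of LowS and LowS_MTEtOH against PM ran from 438 to 1410 (749), the opposite overlap from 1205 to 2464 (1850) and the overlap of both responses to MT-EtOH from 1095 to 2022 (1535). The cause was not tested. With each PM library in 1 of the 2 comparisons the first overlap was 440 and 425, and with each LowS library in 1 of them the opposite overlap was 1219 and 1229, with fewer samples in each comparison.

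The fold minimum of 2 lowers counts by construction, to 1257, 616, 1244, 374, 737, 1229 and 768 in the order above, and the overlaps to 367, 748 and 617. With only the groups compared, and so fewer samples, the counts were 360 for LowS_MTEtOH against PM, 1324 for LowS_MTEtOH against LowS, 412 for NoMo_MTEtOH against LowS_MTEtOH, and 276 and 1091 for the first 2 overlaps, while NoMo against LowS rose to 2184. NoMo_MTEtOH against NoMo rose to 3731 and LowS against PM to 2903, and the interaction had 1100. Without both LowS_MTEtOH libraries NoMo against LowS had 2200, LowS against PM 3291 and NoMo_MTEtOH against NoMo 3378. Each fit of NoMo against LowS that gave about 2200 genes leaves the replicate spread of LowS_MTEtOH out of the shared estimate by construction. Blocked by replicate number the counts were 877 for LowS_MTEtOH against PM, 527 for NoMo against LowS, 1176 for NoMo_MTEtOH against LowS_MTEtOH, 326 for the interaction and 460 for the first overlap. No label says that those numbers mark pairs. The 12 same-numbered pairs of libraries had deviations correlated at a mean r of -0.038, from -0.088 to 0.126. With 2 libraries per group the deviations mirror each other, so these values are few independent checks and cannot exclude pairing.

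Of the 84 list tests 25 passed. With an estimated correlation 0 of the 84 passed, 39 passed with the fry test and 24 with the block. With members by the authors' function added 36 of the 84 passed, and 47 of 105 once the 3 lists too small before were tested as well, and DESeq2 size factors left all 84 on their side of the threshold. The block ended the calls of Fe-S cluster assembly in LowS_MTEtOH against LowS (adjusted p = 0.0664), methionine in NoMo against LowS (0.0875) and iron uptake in the interaction (0.0766), and it added chaperones in NoMo against LowS (0.046) and hydrogenase in NoMo_MTEtOH against NoMo (0.0182). The cause was not tested.

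What depth limits was not tested by varying it. In the simulations, at the depth of these libraries and with 200 of 4976 genes changed, 96.1% of genes changed 4-fold, 60.3% of those changed 2-fold and 6.9% of those changed 1.5-fold were recovered. With 2623 genes called in LowS against PM the share in the data was far larger, so these rates may not hold there.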

Other observations

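The stretch of ribosomal protein genes below was chosen after its values were seen. The ribosomal protein genes did not move as a block. Of the 23 genes from rplQ to rpsJ (3644785 to 3659839 on the chromosome), a run that codes for much of both ribosomal subunits, 20 rose and 1 fell in LowS against PM, with a median log2 fold change of 1.63 over the 23, while the 28 ribosomal protein genes elsewhere had a median of 0.02 (6 higher, 5 lower). In LowS_MTEtOH against PM the medians were 2.19 (20 higher, 0 lower) and 0.31 (10 higher, 0 lower). In NoMo_MTEtOH against LowS_MTEtOH the medians had opposite signs, 1.02 (20 higher, 2 lower) in the run and -0.91 (3 higher, 19 lower) elsewhere. In NoMo against LowS, where no MT-EtOH was given, they were 0.08 (2 higher, 0 lower) and -0.32 (1 higher, 9 lower). With MT-EtOH they were 1.60 (18 higher, 0 lower) and -0.14 (9 higher, 12 lower) in NoMo_MTEtOH against NoMo, and 0.66 (12 higher, 3 lower) and 0.39 (13 higher, 1 lower) in LowS_MTEtOH against LowS.

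In a comparison also added after the values were seen, NoMo_MTEtOH differed from PM in 2323 genes, 1153 higher and 1170 lower. Among the 88 genes raised by at least 3 on the log2 scale in LowS, 38 stood higher and 8 lower than in PM.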
